A study of Mus musculus with 18 samples.

How the data were processed

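Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in Panc02, a mouse pancreatic cancer cell line, in wild-type cells (WT) and in cells in which Nsd2 was targeted with a CRISPR guide (sgNsd2). NSD2 is a methyltransferase that places dimethylation on lysine 36 of histone H3. Per the labels, 4 histone marks were profiled, H3K36me2, H3K27ac, H3K4me1 and H3K27me3, with 2 libraries per mark and genotype and 1 input library per genotype, 18 libraries in all. Libraries were made with a NEBNext Ultra II kit and fly DNA was added at 1 to 2.5% of mouse chromatin, per the series record. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate cultures. The limma and exact permutation p-values thus measure the spread between these libraries, which may be technical. Fisher's exact tests, shifts of windows and permutations of chromosomes take regions, genes, windows or chromosomes as units. Their p-values hold no spread between libraries.

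The deposited files are peak lists, 1 per library. STAR 2.5.1, SAMtools, MACS2 and deepTools are named in the submitters' processing notes, with the builds GRCm38/mm10 and dm6. The MACS2 version, its options and the control of each call are not given in the sources used here. Each peak has a position, a length, a pileup signal, a fold enrichment and −log10 p and −log10 q values, per the file headers. The pileup signal of a peak is the height of stacked fragments in that library, as deposited, and the fold is that height over a local background. The −log10 q values in the deposited lists start between 1.00 and 1.76, so the lists end at a false discovery rate near 0.1. Peaks were called per library, since each library has its own list. No list carries a level scaled to the fly DNA. A peak list therefore shows where a mark stood out from the background of the same library, and cannot show a change in the total amount of a mark. The fold and q values are the authors' and were used only to rank or filter peaks within a list.

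Sequencing depth is not given in the lists and no read counts were used. A background was computed per peak as pileup plus 1, divided by fold enrichment, minus 1, on the assumption that MACS2 added 1 to both. Its lowest value in a library, per 100 bp of the shortest peak, lay between 2.36 and 2.73 in the 12 libraries with more than 10000 peaks, and serves as a measure of effective depth after the caller's scaling. The shortest peak of a list was taken as the fragment length the caller used, because the smallest gap between peaks followed it in every list of more than 10000 peaks (334 bp beside 83 bp, 970 bp beside 242 bp).

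Gene coordinates came from a RefSeq table of GRCm38.p6, the build of the lists. In WT H3K27ac replicate 1, 34.9% of peaks lay within 500 bp of a gene end, against 7.87% after a shift of 10000 bp. All 388 genes of the 15 lists fixed beforehand were found by symbol among 21887 protein-coding genes. The table gives no strand, so a transcription start cannot be told from a transcript end, and windows of 2 kb around either gene end were used where a promoter window had been planned.

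Sequence covered by peaks was the measurement. For each protein-coding gene the covered percent of the gene body (H3K36me2, H3K27me3) or of the gene with 10 kb on either side (H3K27ac, H3K4me1) was computed per library. Genes with a mean of at least 5% over the 4 libraries of a mark were tested with limma 3.58.1 (R 4.3.3, empirical Bayes with trend and robust options), sgNsd2 minus WT, and called at a Benjamini-Hochberg adjusted p under 0.05. Differences are in percentage points. The same fit was made on 10 kb windows along the genome. H3K27me3 had too few genes for a fit, so genes overlapped in both libraries of a genotype were counted. Fixed gene lists were tested with camera (preset correlation 0.01, and an estimated correlation as the alternative). Peaks of the 4 libraries of a mark were merged into regions. A region was gained when both sgNsd2 libraries and neither WT library had at least 1 covered base in it, and lost in the opposite case. Regions called in 1 WT and 1 sgNsd2 library only gave a count for replicate error, which takes no account of lists of unequal length. Covered lengths were compared with a 2-sided exact permutation test, whose smallest p with 2 libraries against 2 is 0.333. H3K27ac and H3K4me1 losses were related to H3K36me2 with a 2-sided Fisher's exact test and with 1000 circular shifts of the windows along each chromosome.

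For the gene fits, named genes were the 12 largest rises and 12 largest falls of a mark among called genes that moved the same way in every pair of libraries, longer genes first where tied, without gene models named Gm or ending in Rik. Nsd2 and the members of a fixed list with the largest differences were added to them, and for regions those among the 5 longest gained and lost. List members past the threshold for H3K27ac are named in full. The fits were tested on simulated data drawn from the libraries' own spread. For H3K27ac, 23.9% of genes changed by 10 points, 65.7% of those changed by 20 and 93.9% of those changed by 40 were recovered, with 1.61% of calls false. For H3K36me2 and H3K4me1 none of the simulated changes was recovered when few genes changed. When most genes shifted by 40 points, 91.4% and 98.8% were recovered. All of these shifts were rises, so recovery of falls was not measured there. For H3K4me1 the simulated shift was larger than the median difference in the data, 11.6 points. Alternatives covered stricter peaks (−log10 q of at least 5), a fold of at least 2, peaks joined within 1 kb, autosomes, the filter, the scale, equal covered length per library, a replicate block, other windows and leaving out each library. These, the tests and the lists were fixed before the peak lists were opened, and alternatives added later are named as such under the dependence on processing. The input lists hold 0 peaks and entered no comparison. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.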

Results

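The peak lists of 16 ChIP-seq libraries described 4 histone marks in WT and sgNsd2 Panc02 cells, with 2 libraries per mark and genotype. H3K36me2 is a broad mark of gene bodies and intergenic sequence, H3K27ac marks active promoters and enhancers, H3K4me1 marks enhancers, and H3K27me3 is placed by Polycomb repressive complex 2. The series is described as a study of the epithelial-mesenchymal transition in pancreatic cancer cells. The number of peaks per library ran from 80356 to 110830 for H3K36me2, from 21501 to 24205 for H3K27ac, from 16107 to 66383 for H3K4me1 and from 6 to 1387 for H3K27me3. Both input lists held 0 peaks.

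Nsd2 itself was looked at first. H3K36me2 peaks covered 0.108% ± 0.153 (SD, n = 2) of the Nsd2 gene body (chromosome 5, 33820676 to 33897966) in WT and 43.9% ± 2.61 (SD, n = 2) in sgNsd2. H3K27ac peaks covered 4.42% ± 0.125 of Nsd2 with its flanks in WT and 4.39% ± 0.231 in sgNsd2 (SD, n = 2 each). H3K27me3 covered 0% of it in each library. Peak lists show neither the edited sequence nor the transcript, so these values do not check the genotype labels. NSD2 places the H3K36me2 mark, and peaks of that mark covered more sequence in the lists labelled sgNsd2. Group names below follow the labels.

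H3K36me2 peaks covered far more of the genome in the libraries labelled sgNsd2, where Dach1, Slitrk5, Lrrtm2 and Hoxa2 were covered from end to end. Covered length was 48.1 Mb ± 7.60 in WT and 348 Mb ± 42.9 in sgNsd2 (SD, n = 2 each), a 7.23-fold difference. Each sgNsd2 library lay above each WT library (exact permutation p = 0.333, the smallest this design allows). Peaks were longer in sgNsd2, with a median of 1777 and 1692 bp against 316 and 324 bp in WT. The smallest gap between peaks was 930 and 970 bp in sgNsd2 and 334 bp in both WT lists. Peak length may thus in part follow the distance over which the caller joined peaks. The longest region gained spanned 499 kb on chromosome 14 (97725839 to 98225101) and contained Dach1, a transcriptional regulator of development. Another of 328 kb on the same chromosome (111506452 to 111834299) contained Slitrk5, a neuronal membrane protein. Outside coding genes, gained regions of 350 kb and 259 kb had Dach1 and Trhde as their nearest genes.

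**Figure D1:**
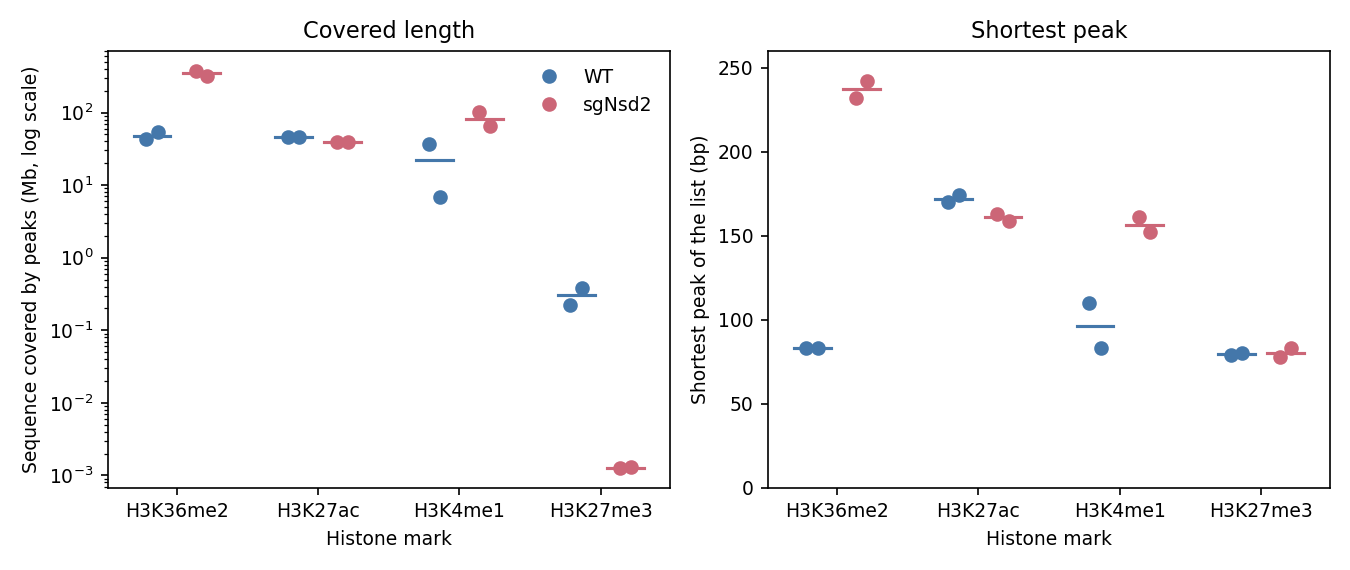
Sequence covered by the deposited peaks of each library (left, Mb, log scale) and the shortest peak of each list (right, bp), for 4 marks, with WT in blue, sgNsd2 in red and bars at group means. For H3K36me2 the covered length was 48.1 Mb in WT and 348 Mb in sgNsd2, and the shortest peak was 83 bp in both WT libraries and 232 and 242 bp in sgNsd2.

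Of 9813 genes tested for H3K36me2, 8437 rose and 59 fell in sgNsd2 (limma, adjusted p under 0.05), with a median difference of 39.4 points. The WT lists covered 1.57 and 1.965% of the genome and the sgNsd2 lists 13.9 and 11.7%. A gene could thus pass the 5% filter through sgNsd2 coverage alone, so the filter favoured rises among tested genes. With no filter, 8992 of 12488 genes rose and 148 fell. The largest rises were ties, since 115 genes went from 0% to 100% covered. By length these were led by Dach1, followed by the deubiquitinase gene Usp17le, the prolactin family members Prl8a2, Prl2c1, Prl7c1, Prl3c1 and Prl8a9 on chromosome 13, the glycosyltransferase gene Gcnt3, Slitrk5, the pregnancy-specific glycoprotein gene Psg17, the olfactory receptor gene Olfr994 and Lrrtm2 (difference 100 points, SE 1.56, limma adjusted p = 0.000329 for each). Among olfactory receptor genes, 121 of 209 tested rose, a smaller share than among all tested genes. They nevertheless made up 70 of the 115 genes that went from 0% to 100%. Most tested genes rose, and 12 of 12 tested H3K36 enzyme genes did too. Among these enzyme genes, Kdm4c rose by 81.1 points and the methyltransferase gene Nsd1 by 76.7 points.

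Few genes lost H3K36me2 in sgNsd2, and leaving out any 1 library cut the 59 falls to between 13 and 26. Cd93, a glycoprotein of endothelial and myeloid cells, and its neighbour Sstr4, a somatostatin receptor gene, lost all coverage on chromosome 2. Cd93 (148436651 to 148443535) went from 78.8% ± 7.56 to 0% (limma adjusted p = 0.00198) and Sstr4 (148395377 to 148396764) from 85.6% ± 20.4 to 0% (limma adjusted p = 0.00778; SD, n = 2 each). The growth factor gene Fgf7 and its neighbour Fam227b, also on chromosome 2, differed by -30.7 and -27.2 points. On chromosome 4 the differences were -42.2 points at the zinc finger gene Bnc2, -42.0 at the scaffold gene Mpdz, -40.2 at Hacd4 and -27.97 at Ccdc171. These genes overlap 1 Mb bins of high local background in both genotypes. Other falls were at the chemokine gene Ppbp (-30.2 points), the killer cell receptor genes Klri1 (-27.9) and Klri2 (-25.7), and Vmn1r40 (-25.35). Of the 59 genes that fell, 20 lay on chromosome 2. With stricter peaks, which left 7 and 10 peaks in the WT lists, 0 genes fell. The longest regions lost were 2 in Bnc2 (8.01 and 7.67 kb) and others of 7.09 to 7.45 kb nearest to Hacd4, Thbd and Mpdz. Hacd4 went the other way among stricter peaks, with a difference of 27.7 points.

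Like most tested genes, fixed lists with at least 2 tested members moved mostly upward in H3K36me2. All 16 tested Hox genes, of 39 listed, rose, with Hoxa2 and Hoxa4 going from 0% to 100%. So did all 4 tested endocrine genes, of 20 listed, including Iapp. The remaining members of these lists did not reach the 5% filter, which favoured rises. Camera called both lists higher than other genes (adjusted p = 0.042 each), and neither held with an estimated correlation (adjusted p = 1 each). In the epithelial list 21 of 26 tested members rose and 0 fell, with the tight junction gene Ocln up by 81.3 points and Elf3 by 77.4. In the mesenchymal list 14 of 17 rose and 1 fell (Col5a1, -5.09 points), and Cdh11 rose by 90.8 points. In the TGF-β list 21 of 23 rose, led by Smad3 at 83.8 and Tgfb1 at 80.5 points. Among Polycomb genes 17 of 19 rose, with Ring1 up by 69.9 and Ezh1 by 67.5 points. Among cell cycle genes 14 of 16 rose, and among housekeeping genes 14 of 15. Among other lists, 2 of 2 acinar, 5 of 6 ductal, 9 of 11 developmental and 3 of 3 hematopoietic genes rose, while the 1 tested endothelial gene, Emcn, fell by 10.4 points. Adjusted over each list alone the counts were the same, except that 6 of 6 ductal genes rose.

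These counts rest on how much was called in each list. The shortest peak, which follows the fragment length, was 83 bp in both WT libraries and 232 and 242 bp in sgNsd2. With each library held to an equal covered length, 231 genes were higher and 268 lower, and leaving out WT replicate 1 or 2 left 2746 or 2979 rises.

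H3K36me2 regions were also counted one by one. Of 149920 regions, 13630 were called in all 4 libraries, 31818 were gained and 11311 lost in sgNsd2. At equal covered length the counts turned to 101 gained and 22602 lost, and without WT replicate 1 or 2 the losses were 38953 or 31914. Patterns that cross the genotypes held 271 to 1156 regions, which takes no account of the longer sgNsd2 lists. Gained regions covered 158 Mb and lost regions 9.72 Mb. On 10 kb windows, 46070 of 65471 tested windows rose and 2218 fell (limma, adjusted p under 0.05), which turned to 4056 and 5992 at equal covered length. The intergenic share of covered sequence, outside coding genes and the 2 kb around their ends, was 56.0% ± 1.20 in WT and 40.2% ± 1.14 in sgNsd2 (SD, n = 2 each). At an equal covered length this order turned, with 57.7% ± 1.15 in WT and 71.3% ± 0.00889 in sgNsd2. The share of sequence common to 2 libraries (Jaccard index) was 0.238 between WT replicates, 0.691 between sgNsd2 replicates and 0.0841 on average across genotypes.

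H3K27ac differed less and was the most alike between replicates. In sgNsd2 it rose over the interferon-induced transmembrane genes Ifitm1, Ifitm2, Ifitm3 and Ifitm6 and the epithelial genes Cldn4, Krt7 and Cdh1, and fell over Cd34, Gpr20, Snai1 and Pdgfrb. Ifitm1 went from 0% to 55.3% ± 1.29 (SD, n = 2; limma adjusted p = 0.000222), the largest rise among the called genes. Cd34, a surface marker of progenitor and endothelial cells, went from 71.0% ± 0.137 to 31.8% ± 2.35 (SD, n = 2 each; limma adjusted p = 0.00107), the largest fall. Covered length was 45.7 Mb ± 0.232 in WT and 39.3 Mb ± 0.0255 in sgNsd2 (SD, n = 2 each; ratio 0.860, exact permutation p = 0.333, the smallest this design allows).

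Of 6407 genes tested for H3K27ac, 240 rose and 389 fell (limma, adjusted p under 0.05). The Ifitm genes are neighbours on chromosome 7, and windows with 10 kb flanks overlap among them, so they are not independent. Ifitm2 rose by 33.95 points, Ifitm3 by 25.9 and Ifitm6 by 24.6. Wnt7a, which encodes a secreted ligand of the Wnt pathway, rose by 35.5 points from 0.564% ± 0.798 (SD, n = 2; limma adjusted p = 0.000222). The phosphatase gene Dusp7 rose by 30.5 points, Dynap by 28.7, Olfr225 by 25.4, the kinase gene Sik1 by 20.4, Hgfac by 19.96 and Misp3 by 19.9. After Cd34, the largest falls were at the receptor gene Gpr20 (53.5% to 17.1%), Mansc1 (43.3% to 11.7%), Erp27 (57.5% to 26.9%), the semaphorin gene Sema7a (53.9% to 24.4%), the pyrophosphate transporter gene Ank (68.5% to 39.5%) and Rassf3 (55.4% to 28.6%). Prss30, the BMP antagonist gene Grem1, Bcl2l14, Pappa2 and the transcription factor gene Nfib fell too, with differences of -25.7, -25.2, -23.5, -22.9 and -22.7 points.

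Of 20 tested epithelial genes 7 gained H3K27ac and 1 lost it (9 and 2 adjusted over the list alone). Camera called the list higher than other genes (adjusted p = 1.05e-05), and the call was lost with an estimated correlation (adjusted p = 0.396). The tested members had a median difference of 3.06 points against -0.476 for all tested genes. Cldn4, a claudin of tight junctions, went from 0% to 25.2% ± 2.99 (limma adjusted p = 0.00107), and Krt7, a keratin of ducts, from 0% to 13.7% ± 4.86 (limma adjusted p = 0.0154; SD, n = 2). Cdh1, which encodes E-cadherin, rose from 2.95% ± 0.310 to 9.86% ± 0.884 (SD, n = 2 each; limma adjusted p = 0.00465). Tjp3, Pkp3, Crb3 and Klf5 rose by 6.64, 4.84, 4.71 and 4.28 points, and Spint2, a protease inhibitor gene, fell by 4.955. The Spint2 difference changed sign among stricter peaks.

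**Figure D2:**
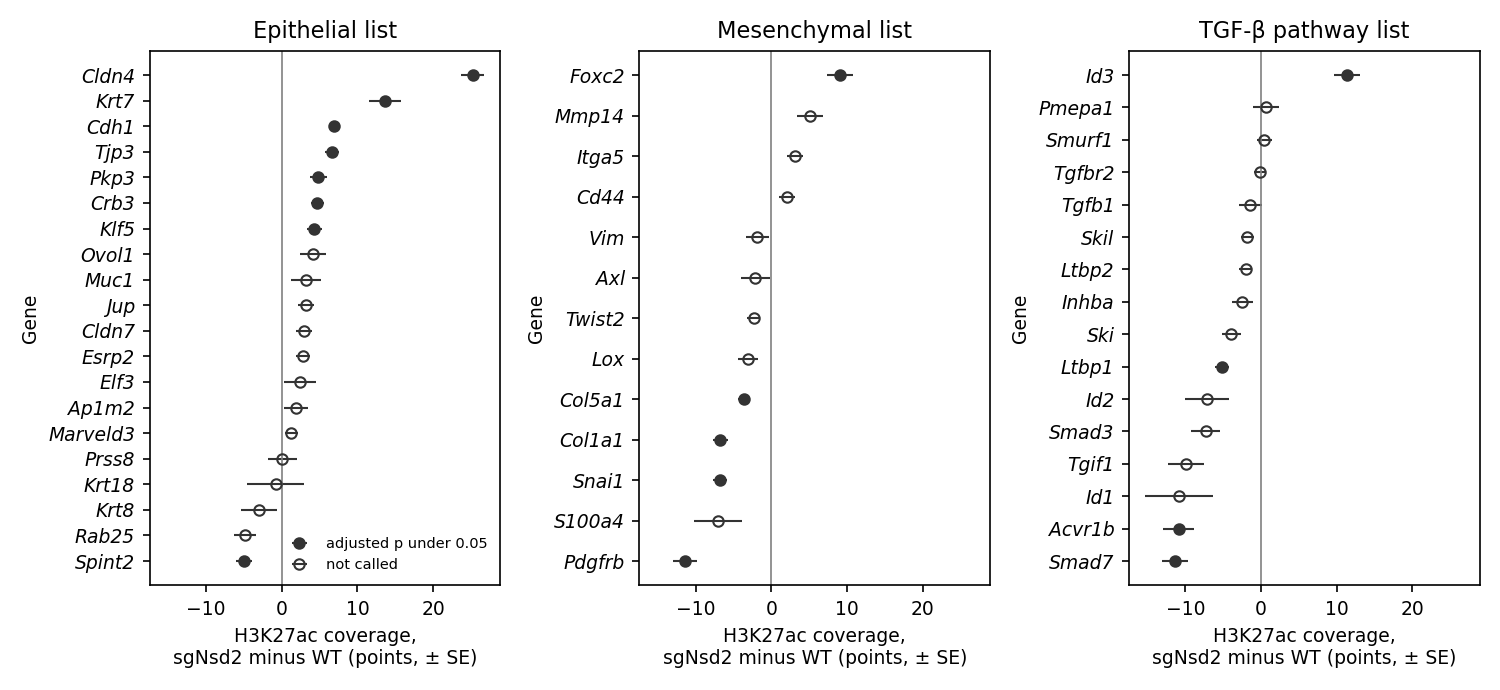
Difference in H3K27ac coverage, sgNsd2 minus WT in percentage points with its SE from limma, for tested members of the epithelial, mesenchymal and TGF-β lists (1 uncalled mesenchymal member not drawn); filled points had an adjusted p under 0.05 (n = 2 libraries per genotype). Cldn4 lies at 25.2 points and Pdgfrb at -11.4.

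In the mesenchymal list 4 of 14 tested members lost H3K27ac and 1 gained it, with the same counts adjusted over the list alone. Pdgfrb, a growth factor receptor gene of mesenchymal cells, fell by 11.4 points (limma adjusted p = 0.0112) and Snai1, a repressor of E-cadherin, fell by 6.76 (limma adjusted p = 0.0104). The collagen genes Col1a1 and Col5a1 differed by -6.75 and -3.61 points. Foxc2 rose by 9.05. The list as a whole was not called by camera (adjusted p = 0.421; 0.76 with an estimated correlation). In the TGF-β list 3 of 16 fell, namely Smad7 (-11.4 points), Acvr1b (-10.9) and Ltbp1 (-5.17), and Id3 rose by 11.4 (1 rose and 6 fell adjusted over the list alone). Camera gave that list an adjusted p of 0.0691, and 0.681 with an estimated correlation. Among 18 cell cycle genes Ccnd1, Cdkn1b and Mdm2 fell (-16.8, -15.5 and -13.3 points) and Cdkn2a rose by 6.996, with the same counts adjusted over the list alone. Mdm2 lies where the local background was highest in both genotypes, and Nfib and Rassf3 also overlap bins of high background. Snai1, Col5a1 and Grem1 lie on chromosome 2, where the local background was 1.103 times higher in WT. H3K27ac covered length on that chromosome was 0.7845 of WT in sgNsd2. Ccnd1 had a difference of 4.88 points at equal covered length. Other calls within lists were 1 each: Rnf2 rose by 6.14 and Cd79a by 9.92 points, and Cdx2 fell by 10.2. None of 19 housekeeping, 18 Hox, 5 ductal, 3 H3K36 enzyme or 1 endocrine genes passed the test. Adjusted over the list alone, 1 H3K36 enzyme gene and 1 endocrine gene (Pdx1) were lower and 1 developmental gene was higher, and the remaining lists kept their counts. No acinar or endothelial gene reached the 5% filter.

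These H3K27ac calls depended on having 2 libraries per genotype. Leaving out any single library left 39 to 59 rises and 37 to 118 falls, and stricter peaks left 44 and 39, while within 2 kb of the gene ends alone limma called 0 genes, with 1426 at an unadjusted p under 0.05. At equal covered length the split turned to 299 higher and 154 lower.

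Of 30309 H3K27ac regions, 16102 were called in all 4 libraries, 1401 were gained and 2522 lost in sgNsd2, against 143 to 174 for the crossed patterns. At equal covered length the counts turned to 3052 gained and 445 lost, without WT replicate 1 or 2 the losses were 5263 or 5183, and without sgNsd2 replicate 1 or 2 the gains were 2508 or 2663. Gained regions included 7.57 kb in Map3k21 on chromosome 8, 7.22 kb in Wnt7a on chromosome 6, 7.19 kb at the syndecan gene Sdc1 on chromosome 12 and 7.17 kb on chromosome 5 (134954937 to 134962107), 8003 bp from Cldn4. The longest, of 8.79 kb, lay 356146 bp from Hs3st1. Of the 5 longest lost regions 3 lay together on chromosome 15 between 73863485 and 73920366 in an intergenic block, and the others were 8.78 kb nearest to Lpin1 on chromosome 12 and 8.35 kb in Tafa1 on chromosome 6. The Jaccard index was 0.710 between WT replicates, 0.738 between sgNsd2 replicates and 0.602 across genotypes. Sequence within 2 kb of gene ends made up 35.02% ± 0.00694 of H3K27ac coverage in WT and 38.6% ± 0.0168 in sgNsd2 (SD, n = 2 each), and 39.2% and 38.6% at equal covered length.

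H3K4me1 peaks covered more sequence in sgNsd2, with long gained regions at Cdh1, Pdlim2 and Sorbs3, Ackr3 and Mbnl1. The gained region at Cdh1 was the longest, at 9.27 kb on chromosome 8 (106603873 to 106613138), and lay inside the gene near the end with the lower coordinate. Covered length was 21.9 Mb ± 21.2 in WT and 82.5 Mb ± 25.5 in sgNsd2 (SD, n = 2 each; ratio 3.78, exact permutation p = 0.333, the smallest this design allows). The 2 WT libraries stood apart, at 36.9 and 6.84 Mb. The shortest peak was 110 and 83 bp in WT and 161 and 152 bp in sgNsd2, so fragment length cannot be told apart from genotype.

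**Figure D3:**
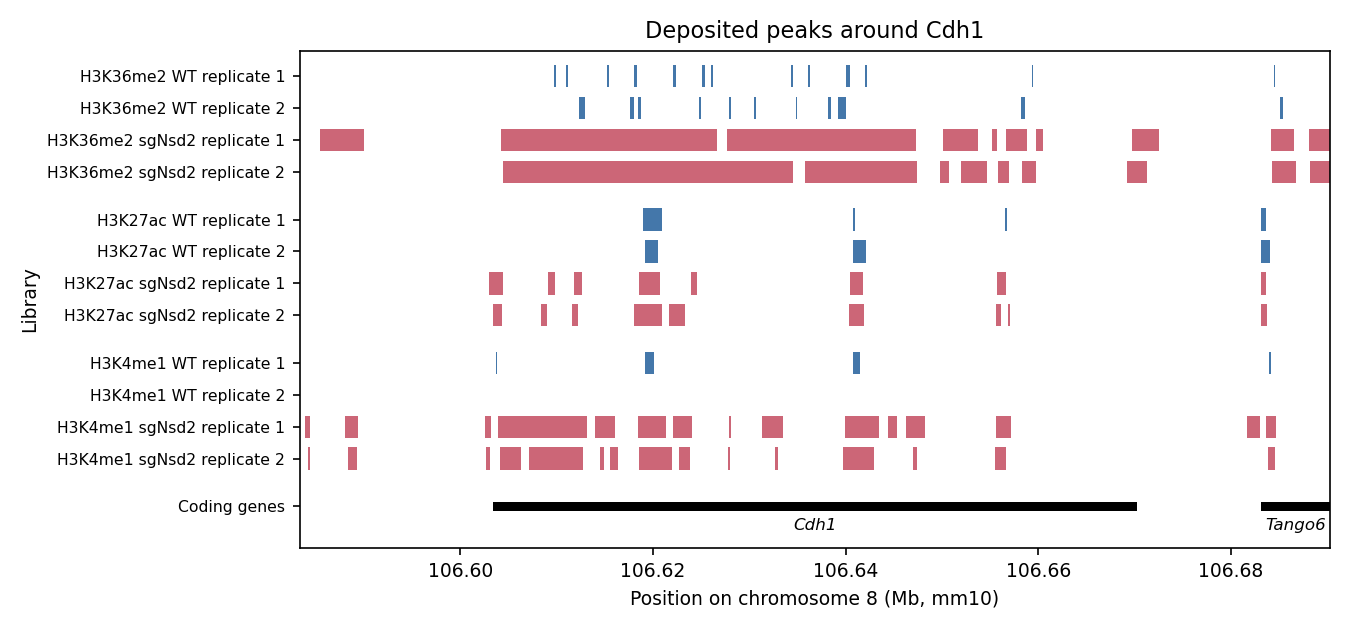
Deposited peaks of H3K36me2, H3K27ac and H3K4me1 within 20 kb of Cdh1 on chromosome 8 (x axis, position in Mb, mm10; 1 row per library, WT in blue and sgNsd2 in red; coding genes in black). In the interval drawn, H3K4me1 peaks covered 31.3 and 21.4 kb in sgNsd2 and 2.06 kb in WT replicate 1, with no peak in WT replicate 2.

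Of 68912 H3K4me1 regions 13994 were gained and 64 lost in sgNsd2, while crossed patterns gave 0 to 1736. At equal covered length the counts turned to 58 gained and 1716 lost. Without WT replicate 2 the losses were 1680, without sgNsd2 replicate 1 they were 181, and without WT replicate 1 or sgNsd2 replicate 2 the gains were 33725 or 33717. The other gained regions among the longest were 8.58 kb over Pdlim2 and Sorbs3 on chromosome 14, 8.31 kb near Dcstamp on chromosome 15, 8.20 kb at the chemokine receptor gene Ackr3 on chromosome 1 and 8.09 kb in the splicing factor gene Mbnl1 on chromosome 3. Lost regions were shorter, with 2.94 kb in Bnc2, 2.39 kb in Macrod2, and 3.47, 2.70 and 2.23 kb nearest to Trib2, Nampt and Marcks. Per gene, limma called 0 of 7495 genes, with 4328 at an unadjusted p under 0.05 and a median difference of 11.6 points. The count turned to 2859 higher with no trend, 1555 around gene ends and 1084 with joined peaks. The largest differences in the epithelial list were 35.7 points (SE 9.17) at Cldn4 and 26.3 (SE 8.80) at Elf3, both with an adjusted p of 0.0564 (limma). Adjusted over the list alone, 17 of 27 tested epithelial, 9 of 20 mesenchymal, 2 of 20 TGF-β, 12 of 20 housekeeping and 9 of 18 Hox genes were higher, and 0 were lower. Among other lists those counts were 5 of 16 Polycomb, 2 of 2 acinar, 4 of 8 ductal, 1 of 3 endocrine, 5 of 10 developmental, 4 of 6 hematopoietic, 2 of 2 endothelial, 0 of 16 cell cycle and 0 of 3 H3K36 enzyme genes. Camera called no list (adjusted p = 0.0699 for the epithelial list). On 10 kb windows 9820 of 29075 rose and 13 fell (limma, adjusted p under 0.05), and without WT replicate 2 or sgNsd2 replicate 1 only 4 and 0 windows passed.

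H3K27me3 gave few peaks, and nearly all were in WT. WT libraries held 803 and 1387 peaks over 0.225 and 0.380 Mb, and sgNsd2 libraries 6 and 7 peaks over 1266 and 1290 bp, 237-fold less on average (exact permutation p = 0.333, the smallest this design allows). Peaks overlapped 97 coding genes in both WT libraries and 0 in both sgNsd2 libraries. Srgap1, a GTPase activator gene on chromosome 10, was covered over 16910 bp ± 2840 in WT (SD, n = 2) and 0 bp in sgNsd2, followed, gene models aside, by the extracellular matrix gene Frem1 (9934.5 bp ± 3685), Myrfl (6635 bp), Tmcc3 (6620.5 bp), Cfap54 (4008.5 bp), Slc24a2 (3693 bp) and the calcium channel gene Cacna1c (3569.5 bp). The longest lost regions were 3.52 kb at the lysozyme gene Lyz1, 3.06 kb in Tmcc3 and 2.87 kb in Srgap1, all on chromosome 10. Of 1987 regions 185 were lost, 1 gained and 1 called in all 4 libraries, and without WT replicate 1 or 2 the losses were 1371 or 790. Of 33 windows of 10 kb past the filter, which only WT coverage could bring there, 30 fell (limma, adjusted p under 0.05), and 2 or 4 without sgNsd2 replicate 1 or 2. WT replicates shared little, with a Jaccard index of 0.0827. A sparse list is no measure of the mark's amount, and 39.1% and 32.97% of WT peak bases lay in 16 bins of 1 Mb with high local background on chromosomes 4 and 10. Srgap1, Frem1, Myrfl, Slc24a2 and Lyz1 lie in those bins and Cfap54 in part, while Tmcc3 and Cacna1c do not.

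The marks were then compared with one another. Cd93, Sstr4, Fgf7 and Sulf2, all on chromosome 2 where the local background was 1.103 times higher in WT, lost coverage in both H3K36me2 and H3K27ac. H3K27ac regions of both WT libraries were lost from both sgNsd2 libraries more often where H3K36me2 had fallen than elsewhere. In 10 kb windows where H3K36me2 fell, 232 of 275 such regions (84.4%) were lost, against 911 of 7835 (11.6%) in windows at least 50% covered by H3K36me2 in both sgNsd2 libraries, 98.1% of which were windows where H3K36me2 rose. The odds ratio was 41.0 (Fisher's exact test, p = 2.44e-159). Against the tested windows called neither way, a reference chosen after the data were seen, the share lost was 573 of 2348 (24.4%) and the odds ratio 16.7 (Fisher's exact test, p = 8.61e-86; shift p = 0.000999). If the labels of the H3K36me2 libraries alone were exchanged, the association would be with windows where H3K36me2 rose. These 232 are a small part of the 2522 H3K27ac regions lost in all. The windows that fell rest on WT H3K36me2 lists in which only 7 and 10 peaks passed the stricter threshold (−log10 q of at least 5). With stricter peaks 0 H3K27ac regions lay in windows that fell, so the association could not be measured there. Neighbouring regions are not independent, and a permutation by 1000 circular shifts of the windows gave a median odds ratio of 1.18 and p = 0.000999, the smallest it can give. For H3K4me1, 22 of 163 regions (13.5%) were lost where H3K36me2 fell and 3 of 5175 (0.058%) in windows covered in sgNsd2 (odds ratio 269, Fisher's exact test, p = 2.34e-31, shift p = 0.000999). The H3K4me1 ratio rests on 3 regions in its smallest cell and was 7.496 at equal covered length and 29.7 against windows called neither way (permutation by shifts, p = 0.00799).

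**Figure D4:**
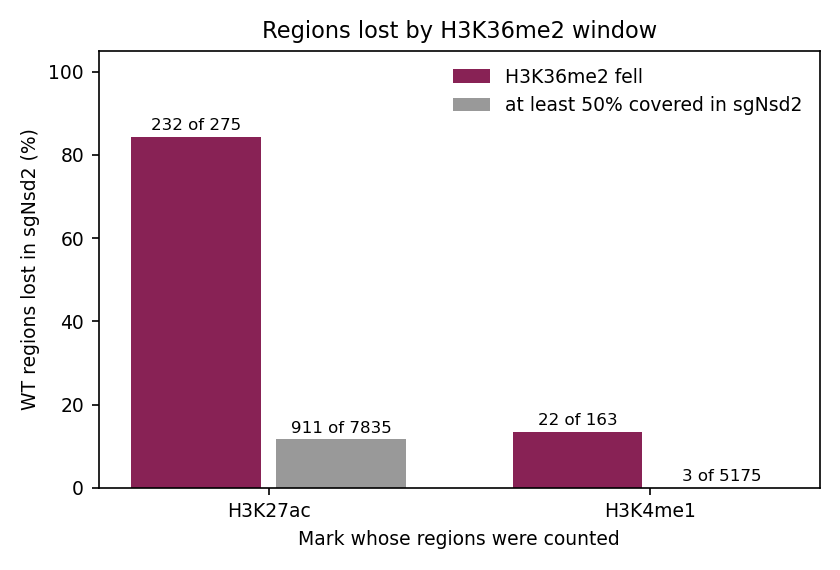
Percent of H3K27ac and H3K4me1 regions of both WT libraries that were called in neither sgNsd2 library (y axis), in 10 kb windows where H3K36me2 fell and in windows at least 50% covered by it in both sgNsd2 libraries, most of which rose, with the counts above the bars. For H3K27ac the shares were 84.4% and 11.6%, and for H3K4me1 13.5% and 0.058%.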

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

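The tests of explanations, the local background and the windows called neither way were chosen after the results were seen. The local background of the peaks, which no comparison used, was uneven along the genome. At 117 to 118 Mb of chromosome 10, where Mdm2 lies, it was 3.64 times the library's lowest value in WT (SD 0.0337) and 4.42 times in sgNsd2 (SD 0.0274), over 6 libraries each of 3 marks. At 83 to 84 Mb of chromosome 4 it was 2.56 times in WT and 3.12 times in sgNsd2. In all, 16 bins of 1 Mb on these chromosomes stood at 1.5 times or more in all 12 libraries. The libraries of a genotype may share a control, so the SDs above may not measure a spread between independent samples.

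The H3K36me2 lists labelled sgNsd2 covered 7.23 times more sequence than the WT lists, although the targeted enzyme places that mark. A difference in effective depth after scaling is argued against, since the background per 100 bp of fragment was 1.05 times that of WT. This background was 2.73 in each WT H3K27ac and H3K4me1 library and 2.56 in each sgNsd2 one. It may thus not follow the sequencing depth of each library, which is not given and was not tested. Fragment length cannot be told apart from genotype: the shortest peak was 2.855 times longer in sgNsd2, with no overlap between groups, and among WT H3K4me1 libraries the one with 83 bp covered 6.84 Mb and the one with 110 bp 36.9 Mb. Exchange of the finished H3K36me2 lists is argued against, since in most of the high bins the ranges of local background did not overlap between genotypes. At 117 to 118 Mb of chromosome 10, WT libraries, both H3K36me2 ones included, lay at 3.59 to 3.68 and sgNsd2 ones at 4.38 to 4.465. Labels exchanged before the calls cannot be told apart, because the background may come from a control matched by label. WT-only regions per Mb went with the WT over sgNsd2 background of the H3K27ac peaks over 19 autosomes. Spearman's rho was 0.288 (permutation p = 0.233) and Pearson's r 0.657 (permutation p = 0.00504, adjusted p = 0.0202). Exchange would turn that relation negative if regions are called more readily where copies are more, but without chromosomes 2 and 12 it was near 0 (0.0049 and 0.016). An even loss of the mark in sgNsd2 that left the remaining domains standing out may also give longer lists, and this was not tested, since no list carries a level scaled to the fly DNA.

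H3K27ac was lost more often where H3K36me2 fell, at an odds ratio of 41.0, or 16.7 against windows called neither way. Fragment length of the H3K27ac lists is argued against, because the shortest H3K27ac peak differed by a ratio of only 0.936 between genotypes. That of the H3K36me2 lists, which define the windows, cannot be told apart from genotype. Complete loss of the DNA is argued against as the whole cause, because both sgNsd2 libraries still held 86.5% of the H3K4me1 regions in those windows. The sgNsd2 H3K4me1 lists were longer, however. At equal covered length, 39 of 42 H3K4me1 regions (92.9%) were lost where H3K36me2 fell and 63.4% in windows covered in sgNsd2. A partial loss of the DNA was therefore not excluded. Copy number of chromosomes 2, 4, 10 and 12 is argued against as the whole cause, because the odds ratio was 50.4 without them. Copy number of other chromosomes, or of stretches within them, was not tested. The direction rests on the H3K36me2 labels, since their exchange alone would make these windows where H3K36me2 rose. Such an exchange before the peaks were called was not excluded, and neither was an effect of genotype on both marks. Differences between the cell populations apart from Nsd2 were not excluded either.

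H3K27me3 peaks were almost absent from sgNsd2. The 16 high bins were chosen for a high local background in both genotypes, so a bin amplified in WT alone could not be among them. In these bins the local background was 1.22 times higher in sgNsd2 at the median (0.935 to 1.296). Amplified DNA in WT alone is thus argued against only for the WT peaks inside these bins. For the WT peaks outside them it was not tested. Fragment length (ratio of the shortest peak 1.01) and effective depth (ratio of the background 1.03) cannot be told apart from genotype, because 6 and 7 peaks measure neither. Yield of the immunoprecipitation and genotype remain open and were not tested.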

How the results depend on the processing

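The planned window around the transcription start was not run, since the gene table has no strand. Windows around either gene end, peaks of at least 250 bp joined within 1 kb, all settings without chromosomes 2, 4, 10 and 12, and the intergenic shares at other windows, stricter peaks or equal covered length were added after seeing the data, as were the windows called neither way. The cause of the changes below was not tested, except that stricter peaks and higher filters leave fewer genes and that a lone library leaves less to estimate the spread from, and is then assumed to vary like the others. Of the WT H3K36me2 peaks only 7 and 10 passed the stricter threshold, against 3447 and 3287 in sgNsd2, so stricter peaks could give no cross-mark value.

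Covered length kept its direction in each setting run. Leaving out a library gave ratios of 6.51 to 8.14 for H3K36me2, 0.857 to 0.863 for H3K27ac, 2.24 to 12.1 for H3K4me1 (12.1 without WT replicate 1, 2.24 without WT replicate 2) and 0.00336 to 0.00568 for H3K27me3. Stricter peaks gave 28098 for H3K36me2, 160 for H3K4me1 and 0.305 for H3K27me3. The H3K27ac cross-mark odds ratio stayed between 16.7 and 97.2 (24.6 to 68.8 leaving out a library of either mark), and the H3K4me1 one between 7.496 and 385 (23.65 to 385). Leaving out H3K27ac or H3K4me1 libraries there was added after seeing the data.

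H3K36me2 genes: rises were 442 with stricter peaks, 5090 at a mean of at least 20%, 231 at equal covered length, and 2746 to 8550 leaving out a library. Falls were 0, 15 and 268 in those settings, 148 with no filter, 36 around gene ends, 31 without chromosomes 2, 4, 10 and 12, and 13 to 26 leaving out a library. Windows called were 14487 at 50 kb, 10048 at equal covered length (4056 higher, 5992 lower) and 22821 to 47607 leaving out a library. H3K27ac genes: rises were 44 with stricter peaks, 55 at 20%, 0 around gene ends and 39 to 59 leaving out a library, and falls 39, 119, 0 and 37 to 118, with 154 falls at equal covered length. Windows, 801 higher and 1717 lower in the main setting, turned to 1164 and 846 at equal covered length, and were 1622 at 50 kb and 0 to 0 leaving out a library. H3K4me1 genes, 0 in the main setting: 11 with stricter peaks, 51 at 20%, 109 on the arcsine scale, 2859 with no trend, 1555 around gene ends, 1084 with joined peaks, and 0 leaving out a library. Windows were 0 at 50 kb and at equal covered length, 5641 with no filter and 0 to 5993 leaving out a library. H3K27me3 windows were 64 with no filter and 2 to 21 leaving out a library.

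Regions gained with stricter peaks and at equal covered length were 2609 and 101 for H3K36me2, 445 and 3052 for H3K27ac and 2814 and 58 for H3K4me1, with 22146 for H3K4me1 where at least 0.5 of the region had to be covered. Regions lost in those 2 settings were 5 and 22602, 715 and 445, and 0 and 1716, and 3 and 3 for H3K27me3. With at least 0.5 of a region covered, losses were 5446 (H3K36me2), 25 (H3K4me1) and 95 (H3K27me3), with peaks joined 7073 (H3K36me2), and on autosomes other than 2, 4, 10 and 12 they were 6357, 37 and 78. H3K27me3 gains were 0 with stricter peaks and on those autosomes. Leaving out a library gave gains of 35112 to 55835, 1777 to 2663, 14076 to 33725 and 1 to 3, and losses of 11641 to 38953, 3075 to 5263, 66 to 1680 and 187 to 1371, in the order H3K36me2, H3K27ac, H3K4me1, H3K27me3.

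The change in intergenic share, sgNsd2 minus WT, was -15.8 points for H3K36me2 and turned to 13.7 at equal covered length and 13.8 with stricter peaks. For H3K27ac it was -1.02, then 1.24 and -0.04996, and -1.41 with gene ends of 5 kb. For H3K4me1 it was 2.48, then -2.32 and -13.8, and for H3K27me3 26.3, then -1.21 at equal covered length and -7.07 with 5 kb. Lists called by camera fell from 2 to 0 for H3K36me2 with an estimated correlation, with the replicate block and without chromosomes 2, 4, 10 and 12. The count was also 0 at equal covered length, where neither of the 2 lists had enough genes to be tested. For H3K27ac they went from 1 to 0 with an estimated correlation (epithelial adjusted p = 0.396) and to 2 without those chromosomes, both lost with an estimated correlation (adjusted p = 0.439 and 0.7499). Of the named-gene values in other settings, 503 for H3K27ac, 379 for H3K36me2 and 126 for H3K4me1 had the same direction and stayed on the same side of the threshold, called or not, 62 and 9 lost their call for H3K27ac and H3K36me2, and 74 gained one for H3K4me1. Leaving out a library, 86 and 48 lost theirs for H3K27ac and H3K36me2. Named genes that turned were Ccnd1 (4.88) for H3K27ac and Met (-3.84) and Prss2 (-16.7) for H3K36me2 at equal covered length, and Spint2 (0.209) and Hacd4 (27.7) with stricter peaks.

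The labels give no shared culture or day for the replicate numbers, and with 2 pairs the numbers do not pair the samples: same-numbered deviations correlated at 0.0211, 0.0328 and 0.336 for H3K36me2, H3K27ac and H3K4me1 genes. With the replicate block H3K36me2 had 8964 rises and 48 falls, H3K27ac 278 and 445, and H3K4me1 7437 and 1, with 24409 H3K4me1 windows and 1 H3K4me1 list called, which was lost with an estimated correlation (adjusted p = 0.989).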

Other observations

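All tests in this part were chosen after the results were seen. Of 5094 genes tested for both marks, 12 fell in H3K36me2 and 323 in H3K27ac, and 9 fell in both, where independent lists would share 0.761 (odds ratio 45.5, Fisher's exact test, p = 2.76e-09). These 9 were Cd93, Sstr4, Fgf7, Sulf2, Fbln7, Col5a1, Bcas1, Nt5c1b and Cd163. Sulf2, a heparan sulfate sulfatase gene, had differences of -9.90 points in H3K27ac and -10.4 in H3K36me2, and the fibulin gene Fbln7 of -8.16 and -14.2. Of the 9 genes 7 lie on chromosome 2, where Cd93 and Sstr4 are neighbours, and 1 on chromosome 12, and the local background was higher in WT on both chromosomes (1.103 and 1.066 times). Neighbouring genes are not independent. Without chromosomes 2, 4, 10 and 12 only 3 genes fell in H3K36me2 and 1 in both (odds ratio 7.905, Fisher's exact test, p = 0.169). With 3 genes left, a shared fall of whole genes cannot be told apart from copy number, although the windows kept an odds ratio of 50.4 without those chromosomes.

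Gains were set against all windows where H3K36me2 had not been called higher, so their odds ratio cannot be compared directly with that of the losses. H3K27ac regions were gained in 1125 of 13325 cases (8.44%) in windows where H3K36me2 rose and in 276 of 4178 (6.61%) elsewhere, counting gained and shared regions, an odds ratio of 1.304 (Fisher's exact test, p = 0.000114; shift p = 0.004). H3K4me1 went the other way, with 45.7% gained where H3K36me2 rose and 71.9% elsewhere.

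H3K36me2 over olfactory receptor genes was counted by chromosome, with no test. In both sgNsd2 libraries at least 50% of the gene was covered in 32 of 68 such genes on chromosome 10, 55 of 287 on chromosome 2 and 14 of 239 on chromosome 7, but in 0 of 63 on chromosome 19 and 1 of 130 on chromosome 9. Over all 1110 the share was 9.64%, against 13.9% of other coding genes.

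H3K36me2 regions lost per Mb were highest on chromosome 2 (13.1) and chromosome 12 (8.32) and lowest on chromosome 16 (0.867). Over 19 autosomes they went with the WT over sgNsd2 background at Pearson's r = 0.657 (permutation p = 0.00504, adjusted p = 0.0202) and Spearman's rho = 0.288 (permutation p = 0.233, adjusted p = 0.233). Without chromosomes 2 and 12 the values were 0.016 and 0.0049, so the relation with this ratio rests on those chromosomes. A relation with the WT background alone was not tested. In H3K36me2 that background was 1.083 on chromosome 15, with 7.80 regions lost per Mb, and 1.001 on chromosome 16. The covered length of H3K27ac, sgNsd2 over WT, gave r = -0.404 (permutation p = 0.0839, adjusted p = 0.168) and rho = -0.314 (permutation p = 0.191, adjusted p = 0.233), and the adjustment ran over the 4 p-values of these 2 relations.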
